A study of Rattus norvegicus with 49 samples.

How the data were processed

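RNA from the CA1 region of the left hippocampus of 49 Fisher 344 rats was hybridised to Affymetrix RAE 230A arrays, 1 array per animal, per the series' design text. The animals were 3, 6, 9 and 12 months old (9 each) and 23 months old (13), per the sample labels. The design text gives the oldest group as 25 months in one place and 23 months in others, and the labels' 23 months was used. It also states that 2 aged animals were removed for poor health, so the replicate numbers of that group are not consecutive. The animals are separate, so p-values measure the spread between animals, and the number of arrays per age limits the precision.

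The deposited values are microarray intensities on a linear scale, computed by the authors with the MAS5 algorithm (per the submitters' processing notes and the series' design text) and scaled over all probe sets to a target of 500 (per the design text). The columns bear that scale: the mean of each array after trimming 2% of probe sets at each end lay close to 500. No version of MAS5 is given in the sources used here. The authors kept probe sets with at least 5 presence calls and a gene symbol, per the design text; presence calls and scan dates are not used here, so batches of arrays were not tested. Correlations of expression with the behaviour scores are not analysed here.

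The table holds 15923 probe sets, of which 57 are controls. In the platform annotation 12789 probe sets had 1 gene symbol, 312 had several and 2822 were not listed. Symbols were updated by Entrez ID through the RefSeq gene table of assembly GRCr8, which matched 12748 of 12783 probe sets and was used for names only. Each gene was represented by the probe set of highest mean log2 signal, which left 10411 genes. A gene was tested where that probe set reached a signal of 100 on at least 5 arrays, which stood in for presence calls and left 8093 genes. Signals under 16 were set to 16 and log2 values were taken from the deposited intensities, with no further scaling; this concerned 0.047% of the tested values. Fold changes are on this log2 scale. No per-sample column of the table was left unused (0), and no 2 of the 1176 pairs of arrays were alike (SD of the log2 difference at least 0.24).

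Tests were made in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with a variance trend) in a single fit of all 49 arrays with a mean per age. The moderated F-test over 5 ages and the contrasts of 23, 12, 9 and 6 against 3 months and of 23 against 12 months were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Of 43 gene lists fixed from textbook knowledge, 42 had at least 5 tested genes and were tested with camera at a preset inter-gene correlation of 0.01, and again with the correlation estimated per list. Genes of the F-test were assigned to the template of largest absolute correlation among 6: a step between each pair of neighbouring ages, a line in months, and a level raised or lowered at the middle ages. Stability was measured on 100 resamplings of animals within ages. Single values were compared with two-sided permutation tests of 100000 resamples.

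The genes named were set by rule: the 10 largest rises and falls among the genes called at 23 against 3 months, the 3 largest in each direction elsewhere, the 4 members of smallest p of each list that passed and at most 2 of each list that did not, 2 genes per template and direction, and 15 genes named in advance, of which 1 is not reported here. Genes with probe sets called in opposite directions are given with both values. Transthyretin (Ttr) and the 5 arrays of high signal for it were singled out after the data were seen.

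The limma step was tested on simulated data shaped as the 23 against 3 month comparison of 8093 genes. It recovered 21, 45, 50 and 50 of 50 genes changed by 0.25, 0.5, 1 and 2 on the log2 scale, with 7 false calls among 173. Of simulated step and linear genes with a change of 1 or 2 on the log2 scale, 50 and 49 of 50 were assigned to their template. Smaller changes were not scored, and the genes called at 23 against 3 months had a median size of 0.34. The assignment of such genes was therefore not measured. In camera 5 of 5 lists shifted by 0.15 and 0 of 15 unshifted lists passed. The simulated genes were drawn independently, so this does not show how often lists of correlated genes pass by chance. Alternatives covered the floor, the signal filter, quantile normalization, median centring, single probe sets, the variance model, array weights, the replicate number as a block, a plain analysis of variance and plain two-sample tests, fits of 2 ages, draws of 9 of the 13 oldest animals, and each array left out in turn.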

Results

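Transcript levels were measured in the CA1 region of the left hippocampus, the field of pyramidal neurons that forms the main output of the hippocampus proper, in Fisher 344 rats of 5 ages. Each animal had its own Affymetrix RAE 230A array. The groups held 9 animals of 3 months, 9 of 6 months, 9 of 9 months, 9 of 12 months and 13 of 23 months, 49 arrays in all. The animals had been trained in a water maze shortly before the tissue was taken, and their behaviour scores are not analysed here. The median signal of an array lay between 208 and 224.9, and 10186 to 10924 probe sets of an array, controls left out, had a signal of at least 100. After the filter on signal and annotation, 8093 genes were tested. The log2 ratio of 3′ to 5′ probe signal, a sign of RNA degradation, was higher at 23 than at 3 months by 0.049 for GAPDH and by 0.110 for actin, differences that did not pass a two-sided permutation test (p = 0.142 and 0.087, both 0.142 after Benjamini-Hochberg adjustment over 2 tests).

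Transthyretin, the secreted protein that is the most abundant transcript of the choroid plexus, set 5 arrays apart. Its signal was 3908, 5108, 8932 and 12003 on the arrays of 3 months replicates 7, 6, 4 and 8 and 16310 on that of 23 months replicate 11. On the other 44 arrays it did not exceed 1123. Counts of genes that moved by over 1.5 times when these 5 arrays were left out are given with that value. Signals of other tissue also varied between arrays. Prox1, a gene of dentate granule cells, ranged from 274 to 1073 among the arrays of 3 months. The haemoglobin gene Hbb stood at 4388 and 659 on 23 months replicates 8 and 5, against at most 210 on the other arrays.

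**Figure D1:**
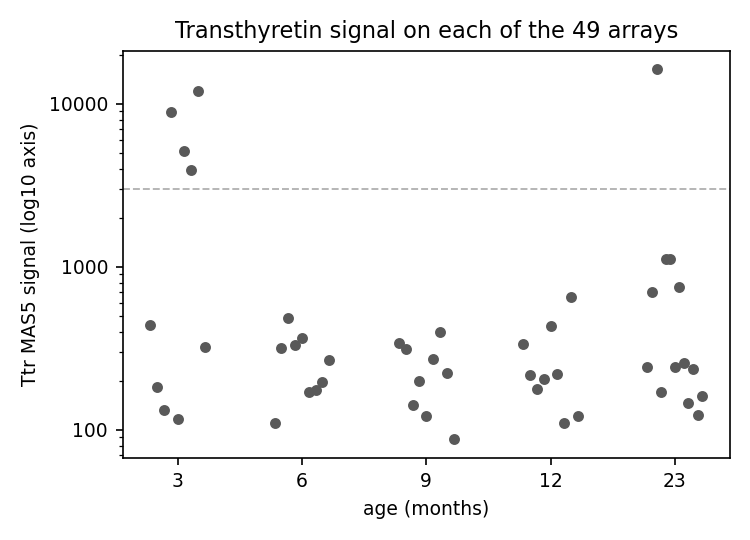
Transthyretin (Ttr) signal on a log10 axis against age in months, with 1 point per array. The dashed line marks a signal of 3000, above which lay 4 arrays of 3 months and 1 of 23 months.

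The first question was which genes differed between any of the 5 ages. Most of the genes found were higher in the oldest than in the youngest animals. In limma's moderated F-test, 152 of 8093 genes passed an adjusted p of 0.05, and 748 had an unadjusted p under 0.05, where chance gives 405. Of the 152 genes, 126 were higher and 26 lower at 23 than at 3 months, and 145 also passed the contrast of these ages. Npc2, which binds cholesterol inside lysosomes, rose from a signal of 1884 ± 104 (SD, n = 9) at 3 months through 2179 ± 125, 2281 ± 230 and 2445 ± 202.2 to 2978 ± 197 (SD, n = 13) at 23 months. C3, the central component of complement, rose from 272 ± 41.2 through 336 ± 54.1, 374 ± 45.8 and 463 ± 70.2 to 700.6 ± 182. The last SD of C3 came with 23 months replicate 9, at 1288, where the other 12 animals lay between 565 and 716.

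Each of the 152 genes was assigned to the closest of 6 age templates by its correlation over the 49 arrays. A change linear in months was closest for 111 genes, 94 rising and 17 falling, which is 73.0% (95% exact binomial interval 65.2 to 79.9). Its leading genes were Npc2 (r = 0.90) and C3 (r = 0.90) among those rising and Sema3c, which encodes a secreted axon guidance protein (r = −0.70), and Tbc1d14 (r = −0.69) among those falling. A step between 12 and 23 months was closest for 21 genes, 17 rising and 4 falling, or 13.8% (8.76 to 20.3). It was led by Cd74, the invariant chain that escorts MHC class II molecules (r = 0.86), and by RT1-Da, a class II α chain (r = 0.84), and, falling, by the synaptic vesicle gene Syngr3 (r = −0.61) and the potassium channel subunit gene Kcnab1 (r = −0.59). A step between 9 and 12 months was closest for 9 genes, led by Ggta1 and Plaat3 rising and Hmox2 and Vmp1 falling. A step between 6 and 9 months was closest for 6 genes, led by Cd83 and Pik3ip1 rising and Rpa3 falling, and a step between 3 and 6 months for 3 genes, led by Nat8f3 and Cdh23. The middle-age template took only Chrm3, a muscarinic acetylcholine receptor gene that was raised, and Rbm17, which was lowered. The binomial intervals above treat genes as independent, which genes measured on the same animals are not. They leave out the spread between animals. A gene kept its template in 74.0% of resamplings of the animals within ages on average for the linear template and in 53.6% for the step between 9 and 12 months, and for 59 of the 152 genes the best correlation exceeded the second best by 0.05. Without a linear template 58.6% of the genes fell to the last step, and over the 757 genes of an unadjusted plain analysis of variance the last step took 22.3% and the linear template 41.3%.

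**Figure D2:**
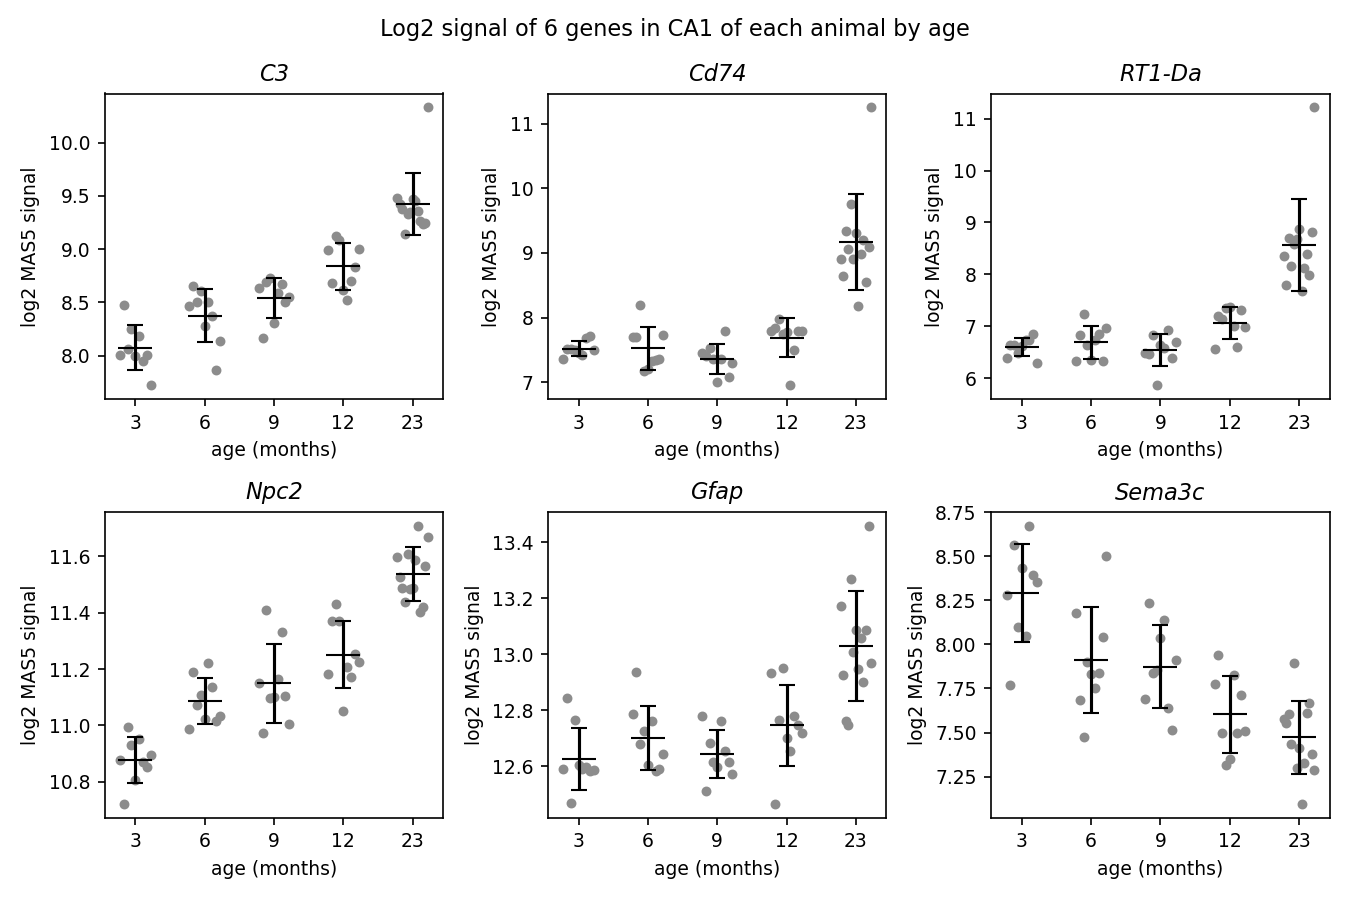
Log2 signal of C3, Cd74, RT1-Da, Npc2, Gfap and Sema3c against age in months. Grey points are animals and black bars are the mean ± SD of each age (n = 9, 9, 9, 9 and 13). C3 and Npc2 were higher at each successive age, and Sema3c was lower at each successive age. Cd74 and RT1-Da were highest at 23 months. For C3, Cd74 and RT1-Da, 23 months replicate 9 stood above the other animals of its age.

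The main comparison set the oldest against the youngest animals. At 23 months the hippocampal CA1 tissue held more transcript of antigen presentation, complement, microglial and lysosomal genes, and most of the genes that differed were higher in the old animals. The lists of these genes share members, so their tests are not independent. Of the 14 complement and 38 lysosomal genes, 10 and 33 are in neither the microglial nor the class II list. limma called 264 genes, 195 higher and 69 lower at 23 than at 3 months, with 1167 genes at an unadjusted p under 0.05. Of the called genes, 9 rose by over 2-fold (6 with signals under 64 set to 64) and 0 fell by over 2-fold, and the median size was 0.34 on the log2 scale. Without the 5 arrays of high transthyretin signal, a comparison chosen after the data were seen, 173 genes were called, 145 higher and 28 lower, and 153 of them were among the 264.

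The genes of the MHC class II complex, which presents antigen to helper T cells, were among the largest rises. RT1-Ba rose by 2.36 ± 0.36 (SE) on the log2 scale, RT1-Da by 1.97 ± 0.21, RT1-Bb by 1.82 ± 0.28 and Cd74 by 1.65 ± 0.18 (adjusted p = 5.96e-06, 1.00e-09, 5.23e-06 and 1.17e-09, with 13 of 13 old animals above the 3-month mean for each). The mean signal of Cd74 was 183 ± 15.2 at 3 months (SD, n = 9) and 676 ± 549 at 23 months (SD, n = 13). The large SD came with 1 animal, 23 months replicate 9, at 2439 for Cd74 and 2382 for RT1-Da, where the other 12 animals lay between 288 and 864 and between 204 and 470. At 3 months the mean signals of RT1-Ba, RT1-Bb and RT1-Da were 48.6, 43.0 and 97.6, under the signal of 100 used in the filter, as were those of Pira2 (40.8), Lgals3 (46.3), Ecrg4 (66.9) and Fcgr2b (92.8). The sizes of the dimmest depended on the floor: with signals under 64 set to 64, the log2 differences were 1.53 for RT1-Ba, 1.17 for RT1-Bb, 0.61 for Pira2 and 0.64 for Lgals3, all still called, while those of RT1-Da and Cd74 stayed at 1.97 and 1.65. Of the 9 measured members of the class II list, 7 rose, and 9 did when adjusted over the list alone (camera adjusted p = 3.56e-20, and 7.24e-06 with an estimated correlation). Ctss, the protease that trims the invariant chain, rose 1.46-fold (adjusted p = 3.99e-07). In the list of MHC class I presentation, which displays peptides from inside the cell, 3 of 17 members rose, and 5 when adjusted over the list alone (camera adjusted p = 1.91e-04, and 0.016 with an estimated correlation). These were B2m, the light chain, at 1.24-fold, and the immunoproteasome genes Psmb9 and Psme1 at 1.63-fold and 1.23-fold. Psme2 was 1.12-fold higher but did not pass (adjusted p = 0.075). In the interferon response list 1 of 18 members passed over all genes, Psmb9, and 6 did when adjusted over the list alone (camera adjusted p = 3.78e-05, and 0.047 with an estimated correlation). Its members Ifitm3, Ifi27 and Irf8 had log2 differences of 0.29, 0.18 and 0.37 that did not pass. With the stricter signal filter the interferon list no longer passed (adjusted p = 0.069).

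Microglia, the resident macrophages of the brain, were the cell type whose markers rose most broadly. Of 26 measured markers 18 rose and 0 fell, and 21 rose when adjusted over the list alone (camera adjusted p = 1.68e-40, and 1.01e-06 with an estimated correlation). The mean log2 signal of the list was higher by 0.55 ± 0.056 (SE) than at 3 months. Fcgr2b, an inhibitory receptor for immunoglobulin G, rose 2.46-fold from 92.8 ± 16.1 to 229 ± 49.0, Gpnmb 1.98-fold from 189 ± 26.3 to 374.5 ± 50.03, Cd53 1.81-fold and Fcer1g 1.70-fold (adjusted p = 3.19e-13, 1.28e-11, 1.04e-09 and 5.72e-12, SD over 9 and 13 animals). Pira2, an immunoglobulin-like receptor gene of myeloid cells, and Lgals3, the galectin of activated phagocytes, rose 2.58-fold and 2.49-fold from signals near the background, with the smaller sizes given above at a higher floor, and Ecrg4 rose 2.07-fold. Among 14 complement genes 6 rose and 1 fell, or 9 and 1 when adjusted over the list alone (camera adjusted p = 2.18e-08, and 0.0023 with an estimated correlation). C3 rose 2.55-fold (adjusted p = 4.71e-15), and C1qa and C1qb, subunits of the molecule that starts the classical pathway, rose 1.56-fold each. The complement inhibitor gene Serping1 rose 1.85-fold, and the member that fell was Vtn, which encodes the adhesion protein vitronectin. Of 22 cytokine and inflammatory signalling genes 5 rose, and 6 when adjusted over the list alone (camera adjusted p = 2.60e-06, and 0.0023 with an estimated correlation). They included Anxa3 at 1.46-fold, S100a4 at 1.72-fold, Il6st, the shared receptor subunit of the interleukin-6 family, at 1.32-fold, and Il18 at 1.30-fold. The other probe sets of Il6st had log2 differences of 0.46, which passed, and 0.042, which did not (adjusted p = 7.28e-04 and 0.701). The Il18 call ended when 3 months replicate 3 or replicate 5 was left out (largest adjusted p = 0.081).

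The acid hydrolases and membrane proteins of lysosomes degrade material taken up by the cell. Of 38 measured genes for lysosomal proteins and proteases 15 rose and 0 fell, and 19 rose when adjusted over the list alone (camera adjusted p = 2.34e-20, and 1.80e-07 with an estimated correlation). Npc2 rose 1.58-fold with the smallest p of all genes (adjusted p = 1.31e-15), Laptm5 1.53-fold and Cd63 1.34-fold. Astrocyte markers rose less, 7 of 25, or 11 when adjusted over the list alone (camera adjusted p = 2.75e-08, and 0.023 with an estimated correlation). Gfap, the intermediate filament of astrocytes, rose 1.32-fold from 6334 ± 503 to 8433 ± 1188 (SD, n = 9 and 13, adjusted p = 2.79e-06), Vim 1.52-fold, S100b 1.17-fold and the glutamate transporter gene Slc1a3 1.14-fold. The other probe sets of Slc1a3 had log2 differences of −0.18 and −0.0088 that did not pass. Of 27 genes of oxidative stress defence and metal binding 3 rose, Gstp1, Nfe2l2 and Gpx1, by 1.27, 1.21 and 1.20-fold, and 11 rose when adjusted over the list alone (camera adjusted p = 0.0026, and 0.047 with an estimated correlation). The Gpx1 call ended without 3 months replicate 5 (adjusted p = 0.062). Mt3 was 1.11-fold higher and did not pass (adjusted p = 0.051). The 41 genes of cytosolic ribosomal proteins and translation factors shifted up together by a small amount, with a median log2 difference of 0.099 and a camera adjusted p of 2.28e-10. That call was lost with an estimated correlation (adjusted p = 0.069), and Rpl34, at 1.10-fold, was the 1 member to pass over all genes, against 16 adjusted over the list alone. The Rpl34 call ended when any 1 of 13 arrays was left out (largest adjusted p = 0.087), and Rps3a, Eef1a1 and Rpl7 at 1.10, 1.14 and 1.08-fold did not pass. Apoe, the lipid carrier of astrocytes, was 1.15-fold higher (adjusted p = 0.033), a call that ended when any 1 of 10 arrays was left out (largest adjusted p = 0.094).

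**Figure D3:**
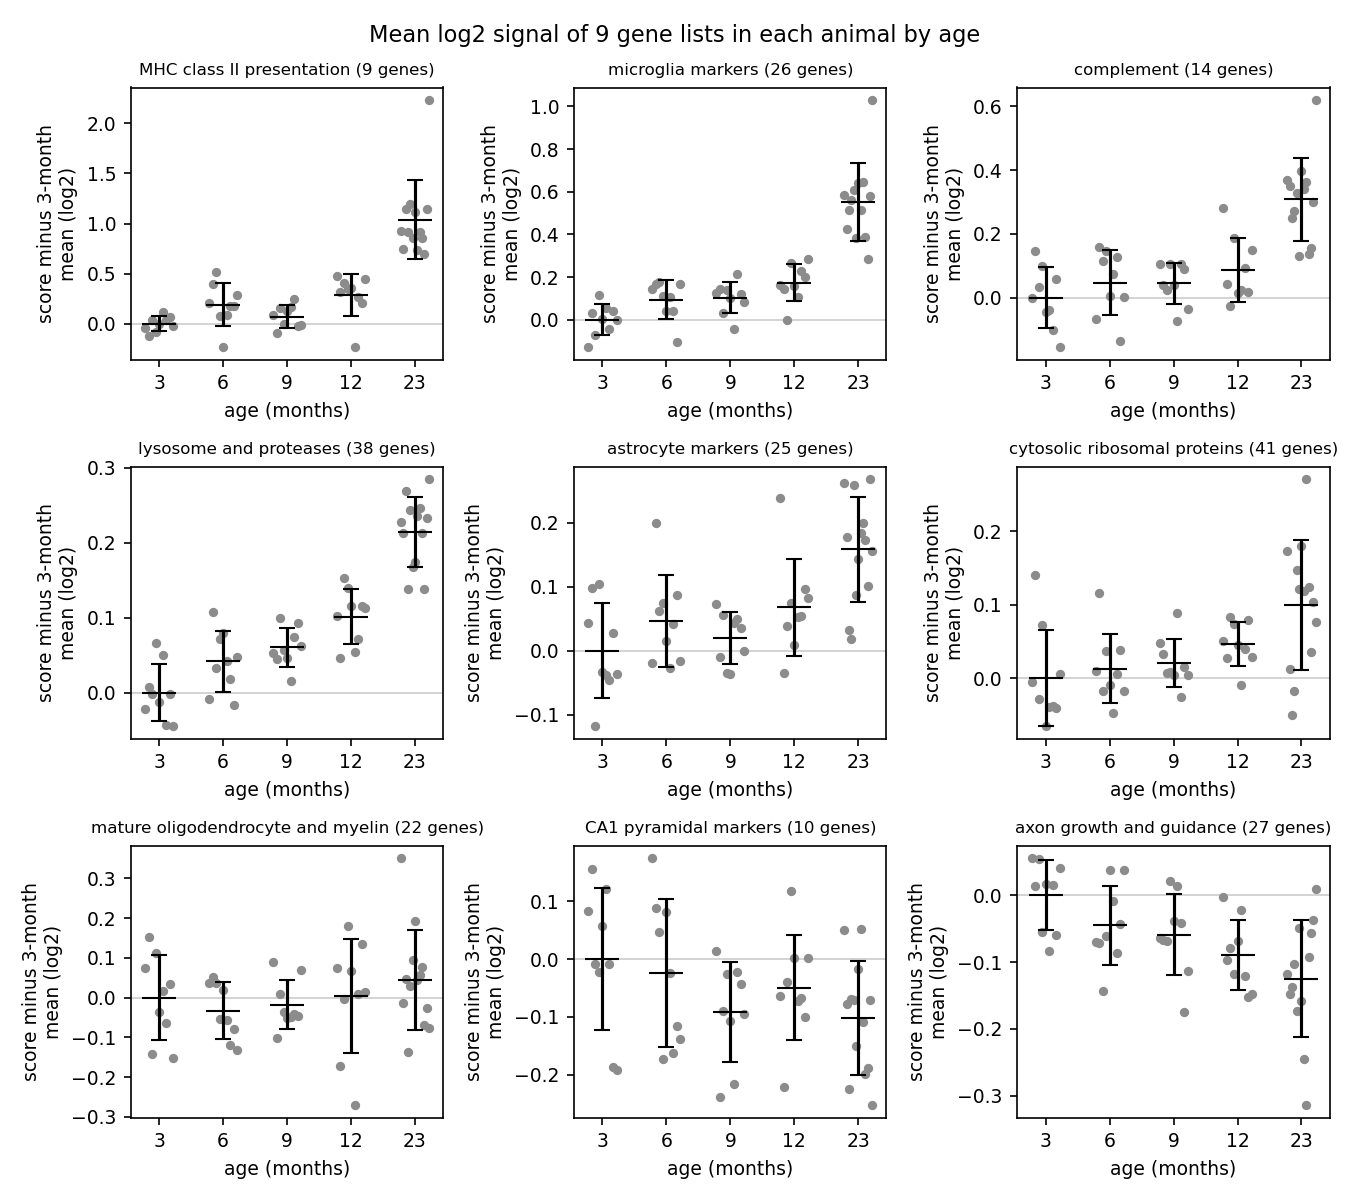
Mean log2 signal of 9 gene lists in each animal minus the 3-month mean, against age in months. Grey points are animals and black bars are the mean ± SD of each age (n = 9, 9, 9, 9 and 13). The class II list was higher by 1.04 and the microglial list by 0.55 at 23 months, against 0.29 and 0.17 at 12 months, and the 6 class II members of at least 100 signal at 3 months were higher by 0.53 at 23 months, while the oligodendrocyte list differed by 0.044 at 23 months.

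The genes that fell at 23 months were fewer and changed less. Sema3c fell by 0.82 ± 0.10 (SE) on the log2 scale, from a signal of 318 ± 58.8 (SD, n = 9) to 179 ± 26.0 (SD, n = 13, adjusted p = 9.94e-08), and was below the 3-month mean in 13 of 13 animals. Glra2, a glycine receptor subunit gene, fell 1.76-fold, Camk4, a calcium and calmodulin dependent kinase gene, 1.54-fold, and Vtn 1.53-fold (adjusted p = 0.011, 0.0038 and 1.59e-05). Lpl, lipoprotein lipase, fell 1.52-fold, the basement membrane collagen gene Col4a5 1.49-fold, Nup50 1.46-fold, Zdbf2 1.40-fold, Nlgn3, a postsynaptic adhesion gene, 1.40-fold and Crabp1 1.37-fold. In the plain two-sample test Glra2, Camk4, Nlgn3 and Crabp1 did not pass after adjustment (adjusted p = 0.156, 0.057, 0.169 and 0.121), and Glra2, Nlgn3 and Crabp1 did not in a fit of these ages alone (adjusted p = 0.090, 0.096 and 0.094). The other probe sets of Camk4 and Nlgn3 had log2 differences of −0.13 and −0.068 that did not pass. Without the arrays of high transthyretin signal, and so with fewer arrays, Nup50, Nlgn3 and Crabp1 did not pass (adjusted p = 0.073, 0.145 and 0.103), with log2 differences of −0.60, −0.41 and −0.47 against −0.54, −0.48 and −0.45 on all arrays. The Nlgn3 and Crabp1 calls also ended when any 1 of 4 and of 3 arrays was left out (largest adjusted p = 0.059 and 0.056). Of 27 genes of axon growth and guidance 2 fell, Sema3c and Nfasc (1.31-fold), and 4 when adjusted over the list alone (camera adjusted p = 4.33e-04, and 0.016 with an estimated correlation). The other probe sets of Nfasc had log2 differences of 0.10 and 0.34 that did not pass. Cntn4 and Epha4 were 1.14 and 1.11-fold lower and did not pass. Of 28 immediate early and activity-regulated genes 2 fell, and 6 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.0020, but 0.144 with an estimated correlation). Nr4a2, a nuclear receptor gene induced by activity, fell 1.33-fold (adjusted p = 0.0038), and its other probe set had a log2 difference of −0.35 that did not pass. Homer1, a postsynaptic scaffold gene, was 1.14-fold lower by its brightest probe set (adjusted p = 0.043), a call that ended when any 1 of 13 arrays was left out (largest adjusted p = 0.125). Other probe sets of Homer1 had log2 differences of −0.73 and −0.78, which passed with every probe set tested (adjusted p = 2.16e-06 and 0.033), and of −0.28 and −0.16, which did not, and which transcript each reads was not analysed here. Egr2 was 1.40-fold lower and Sgk1 1.42-fold higher, without passing.

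Among neuronal markers, the lists of CA1 pyramidal cells and of all neurons were lower by small amounts. Their median log2 differences were −0.10 over 10 genes and −0.041 over 25 genes (camera adjusted p = 0.014 and 0.040), and both calls were lost with an estimated correlation (adjusted p = 0.231 and 0.069). Both calls were lost with the replicate number as a block as well. The neuronal list also lost its call without the arrays of high transthyretin signal (adjusted p = 0.063) and with the stricter signal filter (adjusted p = 0.080). Of the CA1 markers 1 fell, and 1 when adjusted over the list alone: Pou3f1, a transcription factor gene, by 1.25-fold (adjusted p = 0.014, and 0.093 in the plain two-sample test). Dkk3, Wfs1 and Gpr161 were 1.09, 1.11 and 1.14-fold lower and did not pass. Of the neuronal markers 1 passed over all genes, Stmn2 at 1.23-fold lower (adjusted p = 0.032), and 1 fell and 1 rose when adjusted over the list alone. The Stmn2 call ended when any 1 of 6 arrays was left out (largest adjusted p = 0.082), and its other probe set had a log2 difference of −0.21 (adjusted p = 0.0052 with every probe set tested). Camk2g was 1.16-fold higher, and Chga and Elavl4 were 1.15 and 1.14-fold lower, without passing. The list of genes of neurogenesis and developing neurons had a median log2 difference of −0.064 (camera adjusted p = 0.046, but 0.132 with an estimated correlation). That call was also lost with the stricter signal filter, quantile normalization, the choroid plexus score as a covariate and without the arrays of high transthyretin signal (adjusted p = 0.139, 0.067, 0.055 and 0.138). limma called 0 of its 22 members over all genes and 0 adjusted over the list alone, with 5 at an unadjusted p under 0.05. Its members Tubb2b, Crmp1, Tubb3 and Marcksl1 were 1.10, 1.09, 1.10 and 1.10-fold lower, with unadjusted p of 0.011, 0.015, 0.023 and 0.023.

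Of the 42 lists tested, 15 passed, 10 higher and 5 lower, and 10 passed with an estimated correlation. Lists of myelin and mature oligodendrocytes, oligodendrocyte precursors, interneurons, dentate granule cells, CA3 and CA2 cells, endothelium, pericytes, choroid plexus, meninges and lymphocytes did not pass (camera adjusted p = 0.334, 0.523, 0.057, 0.536, 0.161, 0.120, 0.334, 0.334, 0.622 and 0.821). In the oligodendrocyte list 2 of 22 members rose and 1 fell, or 5 and 1 when adjusted over the list alone, among them Qdpr at 1.29-fold higher (adjusted p = 4.82e-07) and Ugt8 at 1.21-fold lower (adjusted p = 0.028, and 0.213 without the arrays of high transthyretin signal, with log2 differences of −0.28 and −0.25). Slco1c1, a thyroid hormone transporter gene of endothelium, was 1.21-fold lower (adjusted p = 0.0020, and 0.060 without the arrays of high transthyretin signal, with log2 differences of −0.28 and −0.25). Abcb1a, the other endothelial marker called, was higher, by 0.49 on the log2 scale (limma adjusted p = 0.030 with every probe set tested). Its other probe set had a log2 difference of 0.21 that did not pass.

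Among lists of neuronal function, those of synaptic vesicles, glutamate receptors, GABA receptors, calcium signalling and sodium and potassium channels did not pass (camera adjusted p = 0.148, 0.148, 0.120, 0.178 and 0.106). Slc17a6, a vesicular glutamate transporter gene, fell 1.34-fold, the potassium channel subunit genes Kcnip4 and Kcnab1 fell 1.21-fold and 1.17-fold, and Amph fell 1.14-fold, and all 4 calls were lost without the arrays of high transthyretin signal, where the log2 differences were −0.41, −0.26, −0.26 and −0.21 against −0.42, −0.28, −0.22 and −0.19 on all arrays. The lists of oxidative phosphorylation, glycolysis, the tricarboxylic acid cycle, the proteasome and chaperones did not pass either (camera adjusted p = 0.294, 0.901, 0.276, 0.120 and 0.120), with Dnaja1 at 1.12-fold lower and Hspb8 at 1.25-fold higher. The Dnaja1 call ended without the arrays of high transthyretin signal (adjusted p = 0.087, log2 difference −0.16 against −0.17), and the Hspb8 call when any 1 of 3 arrays was left out (largest adjusted p = 0.080) and in the plain two-sample test (adjusted p = 0.115). Their other probe sets had log2 differences of −0.077 for Dnaja1 and 0.25 for Hspb8 that did not pass. Cholesterol synthesis and lipid transport gave adjusted p of 0.088 and 0.327, and Cyp51, an enzyme gene of sterol synthesis, fell 1.16-fold (adjusted p = 0.0069, and 0.092 without the arrays of high transthyretin signal, with log2 differences of −0.22 and −0.21). The other probe set of Cyp51 had a log2 difference of −0.33 that did not pass. Collagens, growth factors, glucocorticoid-responsive genes, the circadian clock and senescence gave adjusted p of 0.536, 0.681, 0.555, 0.635 and 0.276, with Timp2 rising 1.22-fold and Gadd45g falling 1.32-fold. The other probe set of Timp2 had a log2 difference of −0.12 that did not pass. The Gadd45g call ended when any 1 of 10 arrays was left out (largest adjusted p = 0.128) and without the arrays of high transthyretin signal (adjusted p = 0.077, log2 difference −0.47 against −0.40). Several genes that mark cells or functions of CA1 showed no difference past the test. Mbp, Camk2a, Snap25, Gria1, Arc, Egr1 and Calb1 had log2 differences of 0.069, 0.031, 0.093, −0.052, −0.16, −0.11 and 0.0092, and Bdnf of −0.38 ± 0.16 (SE, adjusted p = 0.233). Fkbp1b, which encodes a protein that binds and stabilises ryanodine receptors, was 1.21-fold lower (adjusted p = 0.031), a call that ended without the arrays of high transthyretin signal (adjusted p = 0.145, log2 difference −0.29 against −0.28) and when any 1 of 6 arrays was left out (largest adjusted p = 0.063). When every probe set was tested on its own, probe sets of 1 gene passed in opposite directions: Klc1, a kinesin light chain gene, was higher by 0.17 on the log2 scale with one probe set and had a log2 difference of −0.19 with another (adjusted p = 0.041 and 0.046).

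The next comparisons asked how early in life these differences appeared. By 12 months C3 had risen 1.70-fold, from 272 ± 41.2 to 463 ± 70.2 (SD, n = 9 each, adjusted p = 1.01e-05), Nat8f3, an N-acetyltransferase family gene, 1.71-fold (adjusted p = 2.27e-06) and Cdh23 1.77-fold. The Cdh23 call lay at the threshold (adjusted p = 0.049) and ended when any 1 of 33 arrays was left out. Sema3c had fallen 1.61-fold (adjusted p = 3.11e-04) and Rpa3 1.37-fold (adjusted p = 0.0081), the latter lost without the arrays of high transthyretin signal (adjusted p = 0.088, log2 difference −0.45 with and without them). In all, limma called 18 genes, 16 higher and 2 lower at 12 than at 3 months, with 641 at an unadjusted p under 0.05, and with array weights it called 37. The lysosomal list (1 of 38 rose, 6 adjusted over the list alone) and the microglial list (3 of 26, and 12 adjusted over the list alone) passed with camera adjusted p of 2.87e-09 each, and of 5.90e-04 and 0.049 with an estimated correlation. The neurogenesis list had a median log2 difference of −0.099 (camera adjusted p = 0.0024, and 0.049 with an estimated correlation), with 0 of 22 members called by limma over all genes or over the list alone and 4 at an unadjusted p under 0.05. Another 10 of the 42 lists passed with the preset correlation only. They were the lists of class I, class II, complement, interferon, astrocyte, endothelial, ribosomal protein and oxidative stress genes, which were higher, and of axon guidance and choroid plexus genes, which were lower (adjusted p with an estimated correlation = 0.131, 0.131, 0.302, 0.302, 0.302, 0.302, 0.412, 0.256, 0.131 and 0.362). Without the arrays of high transthyretin signal the choroid plexus list was no longer lower (adjusted p = 0.958) and the complement list no longer passed (adjusted p = 0.079).

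At 9 months 3 genes were higher than at 3 months and 0 were lower by limma, with 250 genes at an unadjusted p under 0.05 where chance gives 405, and the plain two-sample test with adjustment called 1 gene, which was not among these 3. Nat8f3 rose 1.58-fold (adjusted p = 1.32e-04), Mgst1, a microsomal glutathione transferase gene, 1.41-fold from 298 ± 47.1 to 416 ± 36.4 (SD, n = 9 each) and Npc2 1.21-fold (adjusted p = 0.0077 for both). Only the Nat8f3 call held without the arrays of high transthyretin signal, where the log2 differences of Mgst1 and Npc2 were 0.35 and 0.29 against 0.49 and 0.27 on all arrays (adjusted p = 0.721 and 0.075). In the same comparison 5, 6 and 5 genes were called without 3 months replicate 2, 9 months replicate 2 and 23 months replicate 9. At 6 months Nat8f3 alone passed, 1.49-fold higher from 280 ± 59.2 to 412 ± 48.2 (SD, n = 9 each, adjusted p = 0.0032), with 231 genes at an unadjusted p under 0.05. Without the arrays of high transthyretin signal 2 genes were called, Nat8f3 among them. Nat8f3 did not pass when only the arrays of these ages were fitted, which called 0 genes by limma, or in the plain two-sample test, which called 0 after adjustment and 238 before.

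Class II genes were also higher at 23 than at 12 months. RT1-Da rose 2.84-fold, Cd74 2.79-fold and RT1-Bb 2.78-fold (adjusted p = 1.09e-05, 4.59e-07 and 0.0018), each above the 12-month mean in 13 of 13 old animals. The signal of Cd74 at 12 months was 210 ± 37.2 (SD, n = 9). limma called 29 genes, 27 higher and 2 lower at 23 than at 12 months, with 665 at an unadjusted p under 0.05. The lower genes were Chrm3 at 1.26-fold and Tbc1d13 at 1.19-fold, calls that ended when any 1 of 12 and of 21 arrays was left out (largest adjusted p = 0.111 and 0.172). In the plain two-sample test, which called 5 genes after adjustment, RT1-Da and RT1-Bb did not pass (adjusted p = 0.072 and 0.082). A fit of these ages alone called 14 genes, and 19, 17, 17 and 16 were called without 12 months replicates 2, 3 and 5 and 23 months replicate 3. With the choroid plexus score as a covariate, added after the data were seen, 18 were called.

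Whether the differences of 12 and of 23 months from earlier ages went the same way was asked with contrasts that share no array. Across the 8093 genes, the 12 minus 3 month and the 23 minus 6 month log2 differences correlated at Pearson r = 0.226 and Spearman rho = 0.197. Genes are not independent replicates, so the value was set against 99 random reassignments of the arrays to ages, of which the highest gave a Pearson r of 0.187. Of the 18 genes called at 12 months, 17 were also called at 23 months in the same direction, 16 higher and 1 lower, where independent lists would share 0.386 and 0.017. Both contrasts use the 3-month arrays, so part of the overlap may come from them. In 50 simulations of unchanged genes 0 were shared at most, a value that leaves out the genes that changed. When the 3-month arrays were split at random into 4 for one contrast and 5 for the other, 20 splits gave a median of 6.5 shared genes (range 3 to 12) out of a median of 7.5 called at 12 months and 151 at 23 months.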

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

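The tests of the microglial and class II rise were chosen only after the result was seen. So was the comparison without the arrays of high transthyretin signal, and with it the tests of the falls lost there. The timing test without the old animal of extreme class II signals rests on an animal picked from these data. The others were set before.

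Single animals stood apart from their group in 9 of 156 groups of 9 animals over 39 genes, where chance flags about 1 in 20 groups, or 7.8 here; the group of 13 animals was not tested. The animal was the highest of its age for RT1-Bb (3 months replicate 5, 72.6, next 49.4), Cd74 (6 months replicate 3, 291.9, next 211.7), Crabp1 (6 months replicate 2, 214.6, next 158.8) and Cdh23 (9 months replicate 3, 156.3, next 103.1). It was also the highest for Gria1 (3 months replicate 9, 960, next 706.6), Bdnf (6 months replicate 9, 487.4, next 271.3), Arc (3 months replicate 1, 1596.3, next 951.4) and Egr1 (12 months replicate 5, 3763.1, next 2821.3). Rpa3 was lowest in 9 months replicate 3 (112.7, next 150.7). Among 1598 tested probe sets without a gene symbol here, 22 were called at 23 against 3 months, 16 higher and 6 lower, or 1.38%. The share was 3.26% among the 8093 genes tested. The probe sets without a symbol were adjusted on their own and each counted, while each gene was counted by 1 probe set, so the shares are not on the same footing.

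The rise of microglial and class II transcripts at 23 months was set against 3 explanations. Choroid plexus tissue in the dissection is argued against by the shift of its own markers, which minus the microglial shift was −0.838 on the log2 scale (95% bootstrap interval −1.57 to −0.0995), and −0.463 without the 5 arrays of high transthyretin signal (−0.749 to −0.179). A smaller neuronal share that raises every glial list alike is argued against by a microglial shift that exceeded the oligodendrocyte shift by 0.506 on the log2 scale (95% bootstrap interval 0.385 to 0.652). An equal rise of every microglial transcript is argued against by 12 of the 25 microglial and class II members of at least 100 signal at 3 months, whose shift differed from the mean shift of 0.49 after adjustment (limma, 5 above and 7 below; highest of 99 other splits 3), with Cd74 at 1.65 and Coro1a at −0.098. More microglia, with part of some signals from background or other cells, more transcript per microglial cell, and age itself stay open and were not tested.

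The share of the 23-month rise reached by 12 months was, over members that these and the microglial list do not share, 49.1% for the lysosomal list (95% bootstrap interval 31.5 to 68.0) and 29.5% for the class II list (13.2 to 44.2), a difference of 19.7 percentage points whose interval, −0.72 to 38.1, holds 0. With the 3 of these class II members of at least 100 signal at 3 months (Ifi30, RT1-DMa and RT1-DMb) the difference was 5.45 (−25.7 to 38.1), and without 23 months replicate 9 it was 17.98 (−3.15 to 38.7). Signals near the floor and that 1 animal cannot be told apart from a later class II rise here, since a difference in timing was not established with all animals either.

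Without the arrays of high transthyretin signal 28 genes fell at 23 months, against 69 with them. Smaller groups may account for this: of 20 random removals of 4 arrays of 3 months and 1 of 23 months, 7 left as few falls (median 32, range 17 to 47). Choroid plexus tissue on the 3-month arrays is argued against, since the 46 genes that lost their fall differed between these and the other 3-month arrays by a median log2 of only 0.017 (quartiles −0.026 to 0.062). All 46 kept a negative difference, but they were chosen as falls on arrays of which most remained, so the kept sign does not bear on either explanation.

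Other splits of the arrays into groups of the same sizes were drawn, 100 for each result with the real one included. Only the real split called as many genes for the age effect (152 genes, highest other 1), for 23 against 3 months (264, highest other 4) and for 12 against 3 months (18, highest other 9). The same held for 9 against 3 months (3, highest other 1) and 23 against 12 months (29, highest other 2). For the number of lists, 2 splits gave as many at 23 months with the real one included (15 lists, highest other 15, median of the others 4) and 1 at 12 months (13, highest other 9, median 3). Chance is thus less likely as the source of these totals but is not excluded, and single lists were not tested this way. The smallest share that 100 splits can show is 1 in 100, and the results were not adjusted for their number. For 6 against 3 months 6 splits gave at least the 1 gene called (highest other 2), so chance stays open there.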

How the results depend on the processing

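The alternatives were fixed before the data were examined, except the fits without the arrays of high transthyretin signal and with the dentate or choroid plexus score as a covariate, which were added after seeing the data. Of 75 named genes called at 23 against 3 months, 46 kept the call under every alternative run, 29 lost it under at least 1 and 0 reversed, and 12 of 33 named genes not called gained a call under at least 1; under the stricter filter 56 were still tested. Genes of dim signal rest on values near the background, where fold changes are least certain. No scaling moved the share of higher calls by 10 percentage points. Unless the number of tests or arrays shows it, the cause was not tested.

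With every probe set tested, 5 genes were called at 9 against 3 months; with array weights 37 at 12 and 8 at 9 months. In the fit with the replicate number as a block, 28 genes were called at 12 and 5 at 9 months, and 269 at 23 months, 190 of them among the 264. Of the 75 named genes called at 23 against 3 months, 12 lost the call in that fit. The numbers were not taken to pair the animals, although same-numbered arrays were on average more alike than others. Of 86 same-numbered pairs, 33 had a residual correlation over 0.1 (mean 0.065, against −0.0063 for other numbers, and 0.187 for number 1). Of 44 arrays with a partner, 11 matched their own number best. A structure shared by replicate number is not excluded by these values. With an estimated correlation 3 lists passed at 12 months. A plain analysis of variance without adjustment called 757 genes, and of the age templates the step between 12 and 23 months took 22.3% of these, against 13.8% of the 152 genes; with no linear template offered it took 58.6% of the 152. Plain two-sample tests without adjustment called 1157, 619, 314 and 238 genes at 23, 12, 9 and 6 against 3 months and 563 at 23 against 12 months; after adjustment 1 and 0 genes were called at 9 and 6 months and 5 at 23 against 12. Fits of only 2 groups called 0 genes at 6 months and 14 at 23 against 12. Without the arrays of high transthyretin signal 173, 1 and 2 genes were called at 23, 9 and 6 against 3 months, with fewer arrays. The dentate score as covariate gave 7 genes at 9 months and the choroid plexus score 18 at 23 against 12.

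Leaving out each array in turn gave 130 to 161 genes for the age effect, 215 to 289 at 23, 15 to 26 at 12, 3 to 6 at 9 and 1 to 1 at 6 against 3 months, and 16 to 33 at 23 against 12. Log2 differences of uncalled genes at 23 against 3 months turned sign: Mbp to −0.0065 with quantile normalization; Camk2a at 23 versus 3 months to −0.070 with the block and −4.14e-04 in draws of 9 of 13 animals; Calb1 to −0.026 with the block, −0.046 without the arrays of high transthyretin signal and −0.012 with the dentate score. Chrm3 turned to 0.0024 without those arrays and to 0.0055 with 1 array left out, as did Rbm17 (0.0017) and Gria1 (0.0022).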

Other observations

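The test of variance between animals was chosen only after the data were seen; the correlations within the oldest group were set before.

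Between 12 and 23 months, 15 of 42 lists passed, 9 higher and 6 lower, and 5 of them with an estimated correlation. These 5 were microglial markers (7 of 26 rose, 22 adjusted over the list alone), class II genes (3 of 9, and 6), complement (3 of 14, and 6 with 1 fall), cytokines (1 of 22, and 3) and lysosomal genes (3 of 38, and 11). Their adjusted p with an estimated correlation were 1.54e-05, 5.76e-05, 0.0038, 0.0038 and 2.10e-04. Lists of oxidative phosphorylation, the proteasome, synaptic vesicles, GABA receptors, calcium signalling and sodium and potassium channels were lower with the preset correlation (camera adjusted p = 0.0062, 0.031, 0.016, 0.031, 0.045 and 0.045). These calls were lost with an estimated correlation (adjusted p = 0.347, 0.247, 0.104, 0.101, 0.123 and 0.101), and limma called 0 of their members over all genes, with 4, 1, 6, 2, 4 and 3 at an unadjusted p under 0.05. The lists of astrocyte, interferon, ribosomal protein and collagen genes were higher with the preset correlation only (camera adjusted p = 2.64e-04, 0.028, 1.21e-04 and 0.012, and 0.164, 0.335, 0.335 and 0.201 with an estimated correlation). limma called 1 astrocyte marker and 0 members of the other 3 lists, with 5, 1, 4 and 3 at an unadjusted p under 0.05.

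One hypothesis was that expression varies more between the oldest animals. The median over genes of the variance at 23 months over that at 3 months was 1.14, and 15 of 100 splits of the 22 arrays gave as large a ratio (highest other 1.28), so a larger spread was not shown.

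A second hypothesis was that other immune scores follow the class II score among the 13 animals of 23 months, with 3 relations tested. The microglial score did (Pearson r = 0.861, permutation p = 8.50e-04, adjusted 0.0026; Spearman rho = 0.808, permutation p = 0.0014), and r was 0.627 without replicates 9 and 8, the 2 animals farthest from the median. The lysosomal score gave r = 0.494 (permutation p = 0.088, adjusted 0.088; rho = 0.429, p = 0.144), and 0.170 without those animals. The complement score gave r = 0.518 (permutation p = 0.071, adjusted 0.088; rho = 0.505, p = 0.082), and 0.4935 without them. Neither of these passed.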
